A study of Mus musculus with 9 samples.

How the data were processed

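Total RNA was sequenced from cells sorted by flow cytometry out of the epidermis of newborn (postnatal day 0) Sox2-GFP reporter mice. Per the labels, GFP-positive cells are Merkel cells, the touch-sensing cells of the epidermis, and GFP-negative cells that carried both SCA1 and CD49F on their surface are basal keratinocytes, used as the control. There were 9 libraries: 3 of Merkel cells and 6 of basal keratinocytes. The titles give sample numbers 1 to 3, and each number has 1 Merkel library and 2 basal libraries, called here the first and the second basal library of that number. The labels do not say how the first and second basal libraries differ, or whether a sample number is an animal, a litter or a pool. The p-values therefore measure only the spread between these sample numbers, part of which may be technical. The 2 basal libraries of a number were averaged in the main fit. Its p-values leave out the difference between first and second basal libraries.

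Libraries were made with a stranded total RNA kit and read as pairs of 125 bases, per the labels' protocols. Reads were trimmed with Trimmomatic, aligned with STAR and quantified with RSEM on mouse build mm10, per the submitters' processing notes, which are used here without versions. The gene annotation and the strand setting of the quantification are not given in the sources used here. The values are TPM, a transcript abundance scaled to the same total in every library, per gene as deposited by the authors, in 1 table with 49672 rows, of which 49671 carry Ensembl gene identifiers and 1 is an added EGFP sequence. TPM keeps no read depth, so the number of reads behind a value is unknown and no counting interval is given. Low values are the least precise, and the values are written with 2 decimals.

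Gene symbols and coordinates come from GENCODE M21, whose build GRCm38 is the same as mm10. Without the version suffix 49326 identifiers matched a symbol, 43749 of them with the same version, and 345 had none. Of the 96 named genes, 18 overlap another tested gene, most of them on the opposite strand. Values of such pairs are uncertain to the extent that reads were divided between them.

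Values were transformed to log2(TPM + 1). The 2 basal libraries of a number were averaged on that scale, which left 3 Merkel and 3 basal values. A gene was tested if its level was 1 TPM or more in at least 3 of the 6 values, whatever the group, and 13822 genes were. A gene near 0 in basal keratinocytes was thus tested only if all 3 Merkel values reached 1 TPM. On the log2(TPM + 1) scale such a gene already lies near or beyond the fold change limit for a call. Its call as higher is thus largely set by the filter. List members low in both groups were left out, so called members among those tested are not shares of whole lists. The test was limma 3.58.1 in R 4.3.3 with a variance trend, two-sided, with Benjamini-Hochberg adjustment. A gene is called higher or lower at an adjusted p under 0.05 and a log2 fold change of 1 or more in size. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes near 0. Levels in the text are mean TPM ± SD over 3 values, the basal value of a number being the mean TPM of its 2 libraries. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9.

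Before the data were examined, 35 gene lists were fixed. They hold Merkel cell, neuronal and signalling genes, keratinocyte states, markers of other cell types that the sort could hold, and signs of RNA quality. The 30 lists with at least 3 tested members were tested with camera, a limma test that compares a list with the other genes, at its preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it. The list of genes behind the sort (Sox2, Ly6a for SCA1, Itga6 for CD49F) is described and not tested. Of the other lists, voltage-gated sodium channels, sensory neurons, endothelium and T cells had too few tested members.

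The rule for named genes was also fixed then. It takes the 10 called genes with the highest and the 10 with the lowest log2 fold change among those at a mean of 10 TPM or more in the higher group and with all Merkel libraries on one side of all basal libraries, leaving out predicted genes and small RNAs. To these it adds the sort genes, the 3 called members of each list with the smallest adjusted p, and the most abundant member of each list of another cell type. Members may be named where a count is 5 or fewer. EGFP and other genes outside this rule are marked as chosen after their values were seen, as are the comparisons of first with second basal libraries; list members set beside a count are examples. Some genes that the rule takes, and some tested list members, are not reported here.

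On simulated values for the comparison of Merkel cells with basal keratinocytes, 13254 genes were tested after 200 were changed. The fit recovered 94% of the genes changed by a log2 fold of 1.5, 94% at 2, 100% at 3 and 98% at 4, and 5 of its 198 calls were false. The simulated noise was independent in every library, with no effect of the sample number and no shift between first and second basal libraries. Only genes with a mean above 5 TPM were changed. These rates are therefore not the error rates of the real comparison.

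Whether the sample numbers pair the libraries was checked by correlating, over the tested genes, each basal value's deviation from its group mean with that of the Merkel library of the same number. The correlations were 0.385, 0.357 and 0.202 for numbers 1, 2 and 3. All were positive and above those of the libraries with different numbers for the same Merkel library, and the pairing comes from the numbers in the titles and this check. A fit with the number as a block is one of the alternatives. The others, fixed at the same time, were pseudocounts of 0.1 and 5, other filters on low values, other scalings between libraries, removal of mitochondrial and small RNA genes, other treatments of the basal libraries, other variance models, other fold change limits and leaving out each replicate in turn.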

Results

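The series measured transcript levels in Merkel cells and basal keratinocytes sorted from newborn mouse epidermis, and its design asks which genes set the 2 cell types apart. Merkel cells are represented by 3 libraries and basal keratinocytes by 6, a first and a second library for each of 3 sample numbers. Read depth is unknown because the values are TPM. Between 13043 and 13649 genes reached 1 TPM in the basal libraries and between 13012 and 13575 in the Merkel libraries. The 7SK and 7SL RNAs, small structural RNAs, took a large part of the total: 7SK held 18.8% to 23.1% of TPM in Merkel libraries and 11.7% to 17.2% in basal libraries. The share of 7SL was 16.1% to 22.5% in Merkel and 18.6% to 25.7% in basal libraries. All small and structural RNAs together held 51.64% in Merkel replicate 2, and 43.35% and 40.76% in Merkel replicates 1 and 3. In basal libraries they held 37.8% to 43.9%.

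The first principal component held 56.7% of the variance and separated Merkel from basal libraries. The second held 17.8% and separated first from second basal libraries. Correlations of log2(TPM + 1) were 0.977 to 0.983 between Merkel libraries. They were 0.960 to 0.982 among first and 0.963 to 0.984 among second basal libraries, and between a first and a second basal library 0.942 to 0.970 for the same number and 0.935 to 0.947 for different numbers.

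The genes used for the sort moved with it. Sox2, the transcription factor whose reporter was sorted on, was at 50.1 ± 4.54 TPM in Merkel cells and 0.0817 ± 0.0729 in basal keratinocytes (SD, n = 3), a log2 fold change of 5.56 ± 0.13 (SE, adjusted p = 2.6e-08). EGFP, the reporter transcript, named after its values were seen, was at 216 ± 34.7 TPM against 9.54 ± 1.70, and in the basal group it was at 1.73 to 3.72 TPM in the first libraries and 13.4 to 18.3 in the second. Itga6, the CD49F integrin chain, was lower in Merkel cells (log2 fold change -1.46 ± 0.18, adjusted p = 0.00029). Ly6a, which encodes SCA1, was at -1.09 ± 0.35 (adjusted p = 0.033). The Ly6a call was lost without Merkel replicate 1 (-0.68), Merkel replicate 2 (-1.13, adjusted p = 0.090), basal replicate 2 (adjusted p = 0.059) or basal replicate 3 (-0.98). Against the second basal libraries alone it was -0.68 (adjusted p = 0.13). The Ly6a call held with the sample number as a block on averaged values (limma adjusted p = 0.00021). It was lost with median-ratio scaling (-0.90) or quantile normalization (-0.92).

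All 5 tested simple epithelial keratins and all 11 tested dense-core vesicle genes were higher in Merkel cells. So were 18 of 22 tested synaptic genes and 11 of 12 tested genes on the list of neuroendocrine and neurogenic transcription factors. Lower were 11 of 17 basal keratinocyte markers and 8 of 35 cell cycle genes. In that order the full lists held 5, 16, 30, 25, 17 and 35 genes, and members low in both groups were not tested. For members near 0 in basal keratinocytes, passing the filter on low values largely sets the call as higher. Each of these lists passed camera at its preset correlation, and none with an estimated correlation (adjusted p = 0.125 for the first 4 lists, 0.32 for basal markers and 0.35 for cell cycle genes). Krt8, a simple epithelial keratin, was higher by a log2 fold change of 7.38 ± 0.17 (SE, n = 3 against 3), and the proliferation marker Mki67 was at -1.67 ± 0.16. Merkel cells and basal keratinocytes differed in 1667 genes, of which 938 were higher and 729 lower in Merkel cells. The changes upward were larger: 145 genes were 8-fold or more higher and 1 was 8-fold or more lower. The 1 was a copy of the small RNA gene Rnu3a (log2 fold change -4.65), and another copy of Rnu3a changed the other way (4.90). In 899 of the higher and 554 of the lower genes every Merkel library lay beyond every basal library. Over all tested genes 5247 were separated in this way, where chance gives 10% of genes for 3 against 3 sample numbers, and 2.38% only if all 9 libraries were independent. The median log2 fold change of all tested genes was -0.15, and scaling each library by its median ratio moved it to 0.02, so that values near 0 are best read against that shift. With that scaling 1091 genes were higher and 442 lower, or 71.2% higher against 56.3% with the values as deposited.

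Ccer2, on chromosome 7 from 28756174 to 28758968 (mm10), had the largest change, with 17787 ± 2489 TPM in Merkel cells and 23.5 ± 6.14 in basal keratinocytes (log2 fold change 9.89 ± 0.16, adjusted p = 1.0e-08). It overlaps Nfkbib on the opposite strand, which was at 9.0 TPM in Merkel cells and 11.3 in basal keratinocytes. The simple epithelial keratin Krt8 followed, at 402 ± 63.6 against 1.43 ± 0.423 TPM (7.38 ± 0.17), and its partner Krt18 at 172 ± 25.2 against 0.898 ± 0.363 (6.53 ± 0.17). The peptide hormone gene Cck was at 177 ± 27.5 TPM against 0.142 ± 0.0225. The transcription factors Pou4f3 and Atoh1, both known for their part in inner ear hair cells and Atoh1 required for Merkel cells to form, had log2 fold changes of 6.72 ± 0.14 and 6.56 ± 0.13. Hepacam2 (6.43), the actin-binding protein gene Avil (5.85) and Krt20 (5.75) were also among the 10 highest. Krt13, a keratin of mucosal epithelia, was at 209 ± 170 TPM and varied most, from 107 to 406 TPM between Merkel libraries; without Merkel replicate 3 its log2 fold change was 5.61 in place of 6.23.

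At the other end, the nuclear RNA Neat1 was at 12.5 ± 1.26 TPM in Merkel cells and 107 ± 13.5 in basal keratinocytes (log2 fold change -2.97 ± 0.14, adjusted p = 8.5e-07). The neighbouring imprinted genes H19 and Igf2, which lie on chromosome 7 from 142575529 to 142578143 and from 142650766 to 142666816, were both lower. H19 was at 1030 ± 370 against 5623 ± 1508 TPM (-2.46 ± 0.32) and Igf2 at 79.9 ± 24.0 against 396 ± 74.6 (-2.28 ± 0.24). The signalling ligand Wnt3a (-2.19), the immediate early gene Fosb (-1.98), the interferon-response regulator Irf1 (-1.95), the procollagen protease gene Adamts14 (-2.31) and the peptidoglycan recognition gene Pglyrp4 (-2.26) were lower too. Fam71a (-2.38) and Cyp2w1 (-1.92) completed the 10 lowest.

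**Figure D1:**
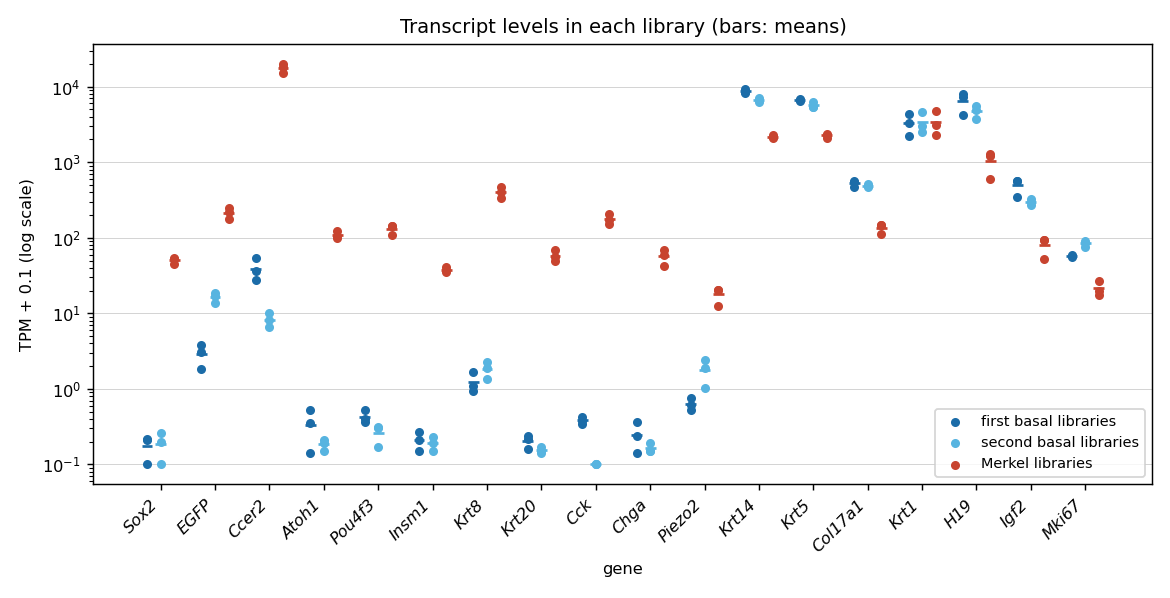
TPM + 0.1 on a log scale for chosen genes, in the 3 first basal, 3 second basal and 3 Merkel libraries; each point is a library and each bar a mean. Sox2 is at 44.9 TPM or more in every Merkel library and at most 0.16 TPM in every basal library, while Krt1 overlaps between the groups.

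Genes of neuroendocrine identity were higher in Merkel cells. All 14 tested members of the list of Merkel cell markers were called higher, with a median log2 fold change of 5.46; Vip, the remaining member, was listed at 0 in both groups. Each member of that list also stands in another list. Of 12 tested genes on the list of neuroendocrine and neurogenic transcription factors 11 were higher. Among the 11 was Insm1 (37.6 ± 3.27 against 0.10 ± 0.0265 TPM), a zinc finger regulator of endocrine cells, besides Atoh1 and Pou4f3. That list also holds genes of RNA-binding proteins, such as Celf3. All 5 simple epithelial keratins were higher. Camera gave adjusted p = 6.7e-23, 5.3e-18 and 6.9e-09 for these 3 lists, and adjusted p = 0.125 for each with an estimated correlation.

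The secretory and synaptic machinery was higher as well. All 11 tested genes of dense-core vesicles and prohormone processing were called, including the granins Chga (56.4 ± 13.1 against 0.105 ± 0.0557 TPM) and Scg5 and the convertase Pcsk1 (log2 fold changes 5.68, 4.42 and 3.84). Of 22 synaptic vesicle and exocytosis genes 18 were higher, including the small GTPase genes Rab3b (5.02) and Rab3c (3.90) and the synapsin Syn2 (4.54). Of 9 neuropeptide genes 8 were higher, with the enkephalin precursor Penk at 185 ± 18.2 against 33.6 ± 6.17 TPM and Calcb at a log2 fold change of 2.85. The camera adjusted p was 1.3e-15, 1.6e-20 and 1.6e-08, and with an estimated correlation adjusted p = 0.125, 0.125 and 0.138.

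Ion channel and adhesion genes of excitable cells followed. Of 25 potassium channel genes 10 were tested and 7 were higher. Kcna4 (3.71), Kcnma1 (3.21) and its auxiliary subunit Kcnmb2 (2.42) had the smallest adjusted p. Of 10 voltage-gated calcium channel genes 5 were higher, including Cacna2d1 (4.09), Cacna1b (1.40) and Cacna1e (1.10). Of 18 neuronal adhesion genes 12 were higher, including Cntnap2 (3.46), Nfasc (3.07) and Cadm3 (2.46). Camera gave adjusted p = 5.3e-09, 2.7e-05 and 8.4e-11, and with an estimated correlation adjusted p = 0.125, 0.138 and 0.125. Of 18 hair cell genes 6 were tested and 3 were higher, Lhx3 (5.49), Espn (2.90) and Lhfpl5 (2.92). Camera gave this list adjusted p = 0.00065, and adjusted p = 0.196 with an estimated correlation. The sensory neuron genes Avil and Tubb3, the 2 tested of the 11 on their list, were higher. Others, such as Nefl, Nefm and Scn10a, were below the level for testing.

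The mechanosensitive channels went both ways. Piezo2, the touch channel of Merkel cells, was at 17.7 ± 4.59 TPM against 1.11 ± 0.386 (log2 fold change 3.20 ± 0.21, adjusted p = 7.2e-06), and the related Piezo1 at 3.95 ± 1.04 against 9.36 ± 1.88 (-1.07 ± 0.20, adjusted p = 0.0027). Piezo1 fell short of a 2-fold change without Merkel replicate 2 (-0.90) or basal replicate 3 (-0.95), and with median-ratio scaling (-0.91). The other 5 tested members were not called. The list as a whole had a median of -0.60, a mean of 0.04 and camera adjusted p = 0.72.

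Of 16 genes of monoamine and glutamate transmission 6 were tested. Tyrosine hydroxylase Th (2.95) and the vesicular glutamate transporters Slc17a6 (2.52) and Slc17a8 (1.18) were higher, and the serotonin transporter Slc6a4 (-1.52) was lower. The members left out were low in both groups. Among them were Ddc and Dbh (0.0167 TPM each in Merkel cells) and Slc18a2 (0.807 TPM in Merkel cells against 1.01 in basal keratinocytes). Camera gave adjusted p = 0.027, which became 0.072 without Merkel replicate 2 and adjusted p = 0.33 with an estimated correlation. Median-ratio scaling, quantile normalization and removal of mitochondrial and small RNA genes gave camera adjusted p = 0.079, 0.073 and 0.083. A filter at 5 TPM turned the median from 0.61 to -0.08 (camera adjusted p = 0.56). Among 8 neurotrophins and their receptors, Ntf3 was higher (36.8 ± 5.73 against 5.14 ± 1.44 TPM) as was Gfra1 (1.74), and Gdnf was among the lower members (-1.23); the list did not pass camera (adjusted p = 0.33), except with no filter on low values (median 0.33, adjusted p = 0.0011).

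Signalling pathways split by member. In the Notch pathway 5 of 15 genes were higher, including the ligand Dll3 (4.14), the target Hey2 (2.97) and the glycosyltransferase Mfng (2.28), and 3 were lower: the receptor Notch1 (-1.15) and the ligands Jag2 (-1.23) and Dll1 (-1.33). Camera gave adjusted p = 0.047. That became 0.10 with the sample number as a block, 0.11 without Merkel replicate 2, 0.057 without basal replicate 1, 0.12 against the second basal libraries alone, and adjusted p = 0.58 with an estimated correlation; median-ratio scaling and quantile normalization gave 0.16 and 0.091. The median, 0.04, turned to -0.25 with a filter at 5 TPM (adjusted p = 0.15), to -0.15 against the second basal libraries alone and to -0.01 without basal replicate 3. In the Wnt pathway Nkd1 (2.17), Wnt5a (2.16) and Notum (2.18) were higher and Wnt4 (-1.80), Wnt3 (-1.10), Wnt10a (-1.05) and Lef1 (-1.03) were lower of 19 tested, with a median of -0.37, a mean of 0.01 and camera adjusted p = 0.74 in the upward direction. In the Hedgehog pathway Hhip (2.47), an inhibitor and target, was higher and the co-receptor Cdon (-1.83) lower of 10 tested (camera adjusted p = 0.42, and 0.037 with a filter at 5 TPM, where the median was -0.60). Gli3 (-1.04) was also called lower, and was at -0.91 without Merkel replicate 2 or basal replicate 1, and at -0.88 with median-ratio scaling. Of the 10 genes 3 were higher in the second than in the first basal libraries (median 0.62), and against the second libraries alone 6 were lower in Merkel cells. Of 18 Polycomb genes 0 were called by limma, with 8 at an unadjusted p under 0.05, all lower (camera adjusted p = 0.19, and 0.035 against the second basal libraries alone).

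Basal keratinocyte markers were lower in Merkel cells in 11 of 17 genes and higher in 0 (median -1.42, camera adjusted p = 1.2e-05, and adjusted p = 0.32 with an estimated correlation). Col17a1, a hemidesmosome collagen, was at 136 ± 20.2 TPM against 508 ± 35.4 (-1.90 ± 0.15), Col7a1 at 32.4 ± 5.27 against 116 ± 14.5 (-1.81) and Sparc at 70.0 ± 7.36 against 197 ± 6.65 (-1.47). The basal keratins stayed abundant, Krt14 at 2187 ± 119 against 7731 ± 279 TPM and Krt5 at 2263 ± 124 against 6130 ± 226. Of 19 suprabasal differentiation genes 0 were called by limma, with 2 at an unadjusted p under 0.05, and Krt1 was at 3360 ± 1226 TPM in Merkel libraries and 3341 ± 1052 in basal libraries (log2 fold change -0.01 ± 0.32). The suprabasal list had a median of -0.01, a mean of 0.02 and camera adjusted p = 0.30 in the upward direction, and 0.044 without Merkel replicate 3 or 0.045 without basal replicate 2.

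Cell cycle genes were lower. Of 35 tested 8 were called lower and 0 higher, with a median of -0.81, including the proliferation marker Mki67 (21.4 ± 4.85 against 70.5 ± 4.84 TPM), the mitotic transcription factor Foxm1 (-1.45) and the kinetochore motor Cenpe (-1.40). Camera gave adjusted p = 5.6e-09, and adjusted p = 0.35 with an estimated correlation. Between second and first basal libraries the cell cycle list had a median of 0.47, with 0 of 35 genes called by limma and 34 at an unadjusted p under 0.05 (camera adjusted p = 7.5e-13, and adjusted p = 0.53 with an estimated correlation). The number called lower in Merkel cells was 20 against the second libraries alone and 5 against the first alone. Of 8 cell cycle inhibitors 0 were called by limma, with 5 at an unadjusted p under 0.05; camera adjusted p was 0.054, with 0.033 under the block, 0.045 against the first basal libraries alone and 0.032 without Merkel replicate 2.

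**Figure D2:**
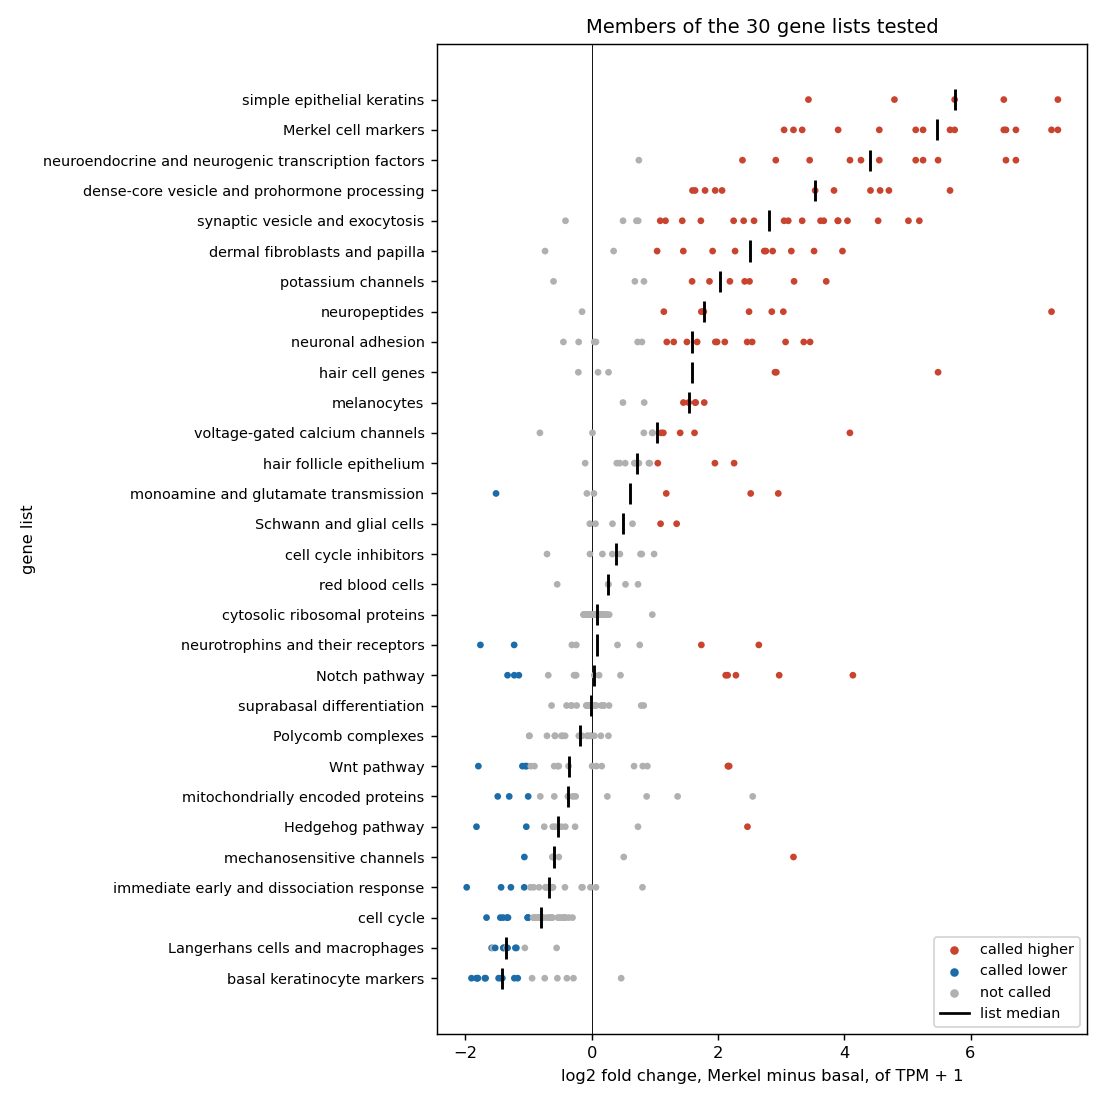
Log2 fold change (Merkel minus basal, TPM + 1) of each tested member of 30 gene lists; each point is a gene coloured by its call, and black bars are list medians. Simple epithelial keratins have the highest median, 5.75, and basal keratinocyte markers the lowest, -1.42.

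Markers of other cell types were measured because sorted fractions can hold them. Of 12 genes of dermal fibroblasts and the dermal papilla, the signalling centre at the base of hair follicles, 10 were higher in Merkel libraries. Col3a1 was at 29.9 ± 5.87 against 0.965 ± 0.228 TPM, Col1a2 at 38.3 ± 4.69 against 5.12 ± 0.847 and Corin at 9.06 ± 1.10 against 0.120 ± 0.0150. The most abundant member, Vim, was at 148 ± 36.2 against 340 ± 102 TPM, and was not called; its log2 fold change was -1.87 against the first basal libraries alone, where it was called lower, and 0.39 against the second. Camera gave adjusted p = 1.5e-09, and adjusted p = 0.125 with an estimated correlation. Whether these transcripts came from Merkel cells or from other cells in the GFP-positive fraction was not tested. Some of the 938 genes called higher in Merkel cells may therefore reflect other cells.

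Of 7 melanocyte genes 5 were higher in Merkel libraries, including the pigment genes Tyrp1 (1.53), Pmel (1.78), Tyr (1.45) and Dct (75.2 ± 12.3 against 33.1 ± 7.73 TPM). Dct was at 10.1 TPM in the first and 56.1 in the second basal libraries, and against the second libraries alone 0 of the 7 passed limma at a 2-fold change (median 0.51). The list's camera adjusted p was 5.3e-06, and adjusted p = 0.28 with an estimated correlation. Of 12 hair follicle genes 3 were higher, Trps1 (1.95), Krt6a (2.26) and Lhx2 (1.05), with camera adjusted p = 1.2e-05 and adjusted p = 0.30 with an estimated correlation. Krt17 was at 732 TPM in the first and 1705 in the second basal libraries, beside 1790 ± 123 in Merkel libraries, and Lhx2 was at 0.49 against the second libraries alone. The Lhx2 call was lost without Merkel replicate 1 (0.86), Merkel replicate 3 (0.94), basal replicate 2 (0.96) or basal replicate 3 (0.96). Of 6 Schwann and glial genes S100b (1.09) and Ednrb (1.34) were higher and the most abundant, Erbb3, was at 38.3 ± 5.15 against 36.7 ± 4.04 TPM. Ednrb was at 0.767 TPM in the first and 4.72 in the second basal libraries, and its log2 fold change was 0.50 against the second alone (adjusted p = 0.078). The list's camera adjusted p was 0.013, with 0.25 against the second basal libraries alone, 0.058 with the block on all 9 libraries and adjusted p = 0.35 with an estimated correlation.

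Of 13 genes of Langerhans cells and macrophages 8 were lower in Merkel libraries, including the pan-leukocyte gene Ptprc (-1.53), the macrophage receptor gene Csf1r (-1.59) and Itgax (-1.33). Cd74, the most abundant, was at 77.1 ± 48.5 against 361 ± 192 TPM and was not called (adjusted p = 0.091), but it was with the block on averaged values (adjusted p = 2.0e-05) or without basal replicate 1 (-2.13, adjusted p = 0.021). With the block on all 9 libraries it was not called (adjusted p = 0.25). Without Merkel replicate 1 it was at -0.87, and without basal replicate 2 at -0.96. These transcripts were concentrated in the first basal libraries, where Csf1r was at 117 ± 46.5 TPM, against 9.72 ± 3.35 in the second. Against the first libraries alone 12 of the 13 were lower, and against the second alone 0 were, with a median of 0.13. The list's camera adjusted p was 0.012, with 0.47 with the block on all 9 libraries, and adjusted p = 0.30 with an estimated correlation.

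**Figure D3:**
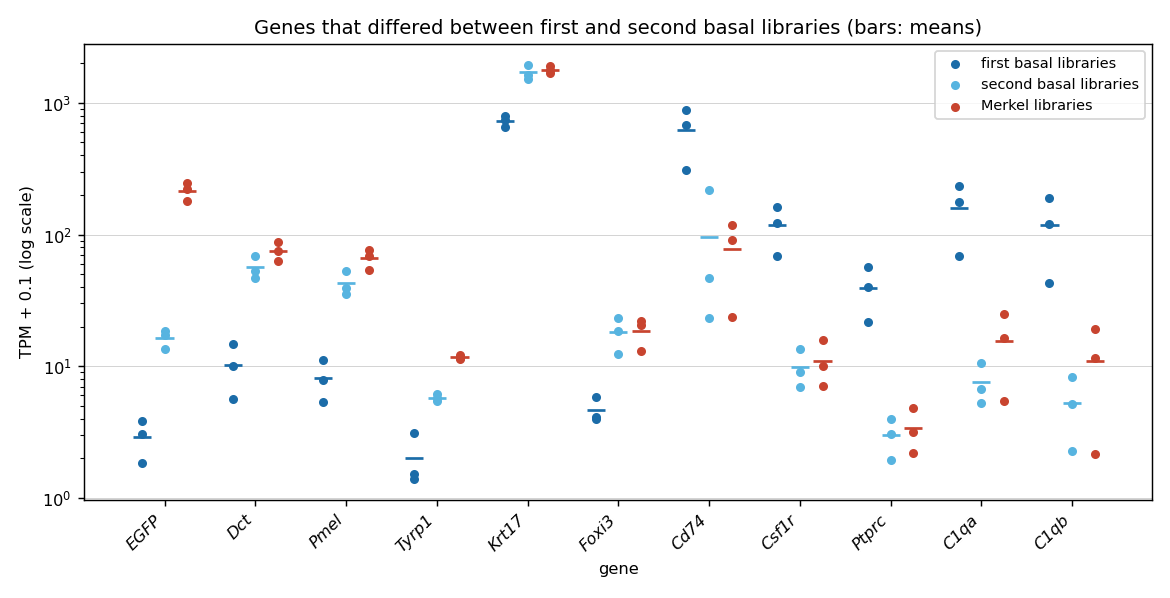
TPM + 0.1 on a log scale for genes that differed between first and second basal libraries, chosen after their values were seen, with the Merkel libraries beside them; each point is a library and each bar a mean. Csf1r lies at 69.2 TPM or more in the first basal libraries and at 13.4 or less in the second.

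Of 5 red blood cell genes 0 were called by limma and 0 had an unadjusted p under 0.05, with camera adjusted p = 0.53, and Hba-a1 was at 174 ± 135 against 131 ± 74.3 TPM. Its log2 fold change ranged from -0.37 to 1.19 when single replicates were left out, and was never called. Pecam1, the 1 tested endothelial gene, was at 1.76 ± 0.433 against 0.408 ± 0.0785 TPM, just short of a 2-fold change (0.97, adjusted p = 0.00092). It passed without Merkel replicate 1 (1.01), Merkel replicate 2 (1.05) or basal replicate 3 (1.00), and with median-ratio scaling (1.06). None of the T cell genes reached the level for testing.

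Signs of handling and RNA quality were also compared. Of 20 immediate early and dissociation genes 4 were lower in Merkel libraries and 0 higher. Zfp36 was at -1.28, and at -0.91 without Merkel replicate 2; Fosl1 was at -1.07, and at -0.86 without Merkel replicate 2 or -0.83 without basal replicate 3. The list's camera adjusted p was 0.039, with 0.077 without Merkel replicate 3, 0.058 without basal replicate 3 and 0.10 against the first basal libraries alone, and adjusted p = 0.69 with an estimated correlation. Of 13 mitochondrially encoded genes mt-Nd5 (-1.49), mt-Nd6 (-1.31) and mt-Nd4 (-1.01) were lower. The mt-Nd4 value was -0.88 without Merkel replicate 2, -0.82 without basal replicate 1, -0.96 without basal replicate 3 and -0.81 with median-ratio scaling, short of a 2-fold change. The list did not pass (camera adjusted p = 0.65). The share of all mitochondrial transcripts was 2.82% to 3.74% in Merkel and 2.44% to 4.47% in basal libraries. Of 77 cytosolic ribosomal protein genes 0 were called by limma, with 1 at an unadjusted p under 0.05, and the list lay slightly above the other genes (median 0.08, camera adjusted p = 0.0079). That was 0.16 against the first basal libraries alone, 0.056 without Merkel replicate 1 and adjusted p = 0.79 with an estimated correlation.

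By camera at its preset correlation 17 lists were higher and 4 lower, and 0 passed with an estimated correlation, while 19 passed by fry. Adjusted over the list alone, the counts of called members were equal to those adjusted over all genes tested in all 30 lists. Other divisions of the same 6 values into 3 and 3 gave 7 to 23 lists by camera, and 0 or 1 called genes by limma. Each of them has Merkel and basal values on both sides, so these counts do not show what no difference would give.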

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

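The comparison of single basal libraries with the other basal libraries was planned, and no test was added for it after its result was seen. Among the 96 named genes, 2 had 1 of the 6 basal libraries far from the others, where chance alone gives about 1 in 20. Cacna1b, a calcium channel subunit gene, was at 0.33 TPM in the first basal library of number 1, and the nearest other basal library was at 0.05 TPM. Nfasc, the adhesion gene neurofascin, was at 0.12 TPM in the second basal library of number 1, and the nearest other was at 0.04 TPM. Both values are near 0, where TPM is least precise, and the Merkel means were 1.89 TPM for Cacna1b and 7.75 TPM for Nfasc.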

How the results depend on the processing

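The alternatives reported here were planned, and none was chosen after its result was seen. Of 96 named genes 67 kept their call under every alternative of pseudocount, filter, scaling, library use, variance model and left-out replicate (the other fold change limits were applied to counts only). With the preset correlation 19 of 30 lists kept their call under every alternative. Some genes and lists without a call changed sign. Hba-a1 went from 0.26 to -0.37 without Merkel replicate 3, and the median of the red blood cell list from 0.26 to -0.26 against the first basal libraries alone. With a pseudocount of 0.1, 1191 genes were higher and 1281 lower, so that lower genes outnumbered higher ones; the cause was not tested. With a pseudocount of 5, 377 were higher and 186 lower, which follows from the smaller fold changes it gives. A filter at 5 TPM left 9864 genes, of which 486 were higher and 449 lower. Median-ratio scaling gave 442 lower. It moved the median log2 fold change of all tested genes from -0.15 to 0.02, a shift that by itself leaves fewer genes beyond the lower limit. Without a minimum fold change the genes higher in Merkel cells numbered 1824 and the genes lower in Merkel cells 3941. With a log2 fold change of 2 or more they numbered 360 and 11. More genes at a looser limit and fewer at a stricter one follow by construction. The excess of lower genes without a limit does not, and its cause was not tested. Camera with an estimated correlation gave 0 lists higher and 0 lower. By fry, 19 of 30 lists passed.

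With the sample number as a block on the averaged values, 960 genes were higher and 759 lower. The block ended the call of the Notch list (adjusted p = 0.10, over all alternatives 0.0076 to 0.16), gave one to the cell cycle inhibitors (adjusted p = 0.033, range 0.021 to 0.097) and to Cd74 (adjusted p = 2.0e-05, range 2.0e-05 to 0.98), and on these averaged values changed no other call among the named genes and lists. On all 9 libraries the block gave 916 higher and 564 lower. It ended the calls of the lists of Langerhans cells and macrophages (adjusted p = 0.47), Schwann cells (0.058) and the Notch pathway (0.15), and of Ptprc (0.28), Csf1r (0.28), Itgax (0.19), Dct (0.13), Pmel (0.086), Tyr (0.084), Ednrb (0.080) and Lhx2 (0.060), and gave one to the cell cycle inhibitors (0.021). In the same libraries duplicateCorrelation, with a consensus of 0.127, gave 918 and 568; the list tests were not run under duplicateCorrelation.

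Against the first basal libraries alone 1031 genes were higher and 924 lower, and against the second alone 893 and 706. Against the second alone the median of the Langerhans cell and macrophage list changed sign to 0.13, as did Ptprc (0.13) and Csf1r (0.13). Leaving out 1 replicate at a time gave 877 to 1007 genes higher and 594 to 870 lower, 16 to 18 lists higher and 3 to 4 lower. Depth is unknown for TPM values, so its limit on low genes cannot be given.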

Other observations

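All tests of explanations here, the limits used to read them, the list of imprinted genes and the comparison of second with first basal libraries were chosen only after the results were seen. Imprinted genes, expressed from 1 parental copy, moved in both directions. Of 25 tested, 6 were higher in Merkel cells and 2 lower, H19 and Igf2. The higher ones were Rian (21.3 ± 7.82 against 3.22 ± 2.20 TPM, log2 fold change 2.59), Nnat (1.66), Peg10 (1.42), Ndn (1.29), Snrpn (1.22) and Dlk1 (1.04). Against the second basal libraries alone Snrpn (0.87), Ndn (0.98) and Dlk1 (0.93) fell short of a 2-fold change. The other 17 were not called.

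Second and first basal libraries differed in more than their number. With the sample number as the pair, limma called 103 genes higher and 444 lower in the second libraries. All 13 genes of Langerhans cells and macrophages were lower (median log2 fold change -3.20), with the complement gene C1qa at 7.42 against 159 TPM. Of 7 melanocyte genes 6 were higher (median 1.87), with Pmel at 42.4 against 8.0 TPM, and 7 of 12 hair follicle genes were higher (median 1.13), with Foxi3 at 18.0 against 4.54 TPM. Of 10 Hedgehog pathway genes 3 were higher, and 3 of 5 red blood cell genes were lower. Krt14 was at 8781 TPM in the first and 6681 in the second libraries.

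The EGFP transcript was at 16.3 ± 2.53 TPM in the second and 2.80 ± 1.00 in the first basal libraries, a gain equal to 6.25% of the Merkel level. If Merkel cells, or free RNA or reads of the whole GFP-positive fraction, had brought it, Merkel cell markers would gain a like share. The median gain over 14 markers was -0.0937% of their Merkel level. Piezo2 alone gained as much (6.53%), and the other 13 gained far less than EGFP. Merkel cell markers cannot show whether other cells of the GFP-positive fraction brought EGFP. Melanocytes may carry it, since 6 melanocyte genes were higher in the second libraries, but the GFP-negative gate would be meant to remove cells that carry GFP, members of 3 other lists of cell types were higher too, and these sources cannot be told apart. Beyond melanocytes, no biological explanation of the EGFP difference was tested, because the labels do not say how the libraries differ.

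The lower macrophage and Langerhans cell transcripts in Merkel cells rested on the first basal libraries. Of the 8 genes called lower, 0 passed limma at a 2-fold change against the second basal libraries alone, which is consistent with immune cells in the first basal libraries. Lower expression in Merkel cells than in basal keratinocytes would leave the list well below 0 there, and its median was 0.13. The most abundant member, Cd74, was at 626 ± 292 TPM in the first and 95.5 ± 106 in the second libraries. A sort on SCA1 and CD49F would be meant to remove such cells, and the sort gates were not examined here.

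Keratinocyte transcripts in the Merkel libraries were weighed against admixed basal keratinocytes. Krt14 stood at 28.3% of its basal level (log2 fold change -1.81), while the suprabasal list had a median of -0.0059 with an SD over its members of 0.358, which argues against 1 share of basal keratinocytes as the source of the suprabasal transcripts. For the basal keratins such a share may be the whole source, although a sort for GFP would be meant to remove basal keratinocytes: of 1507 transcripts at 50 TPM or more in the basal libraries, 1, Neat1, lay below the Krt14 fold change by more than 2 standard errors, with the errors of both values combined. At 10 TPM or more 7 of 7275 did, and without predicted genes and small RNAs 3 did: Neat1 (11.7% of its basal level), Fam71a (13.9%) and Adamts14 (16.4%). These go against a single share as the whole source, but they are few and were looked for after the values were seen, so that admixture and expression by Merkel cells cannot be told apart.

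Other divisions of the same values were fitted in the same way. The real division of the 6 values gave 1667 genes and the highest of the others 1, and as large a count came from 1 of 10 divisions, too few for a share under 0.05. The other 3 divisions that part all 3 pairs gave 0 genes by limma. For gene lists by camera the real division gave 21 and the highest other 23, and 2 of 10 divisions gave as many. Every other division has Merkel and basal values on both sides, in unequal numbers. It keeps part of the difference between the cell types and adds the rest to the spread. These divisions therefore cannot show how many genes or lists would pass without a difference. The number of lists passing at the preset correlation is not taken by itself as evidence of a difference between the cell types. For second against first basal libraries the real order gave 547 genes and the highest other 0, and 1 of 4 orders gave as many, again too few for a share under 0.05. The other orders likewise have first and second libraries on both sides.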
